A study of Arabidopsis thaliana with 24 samples.

How the data were processed

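RNA from the whole aerial tissue of 2-week-old, soil-grown Arabidopsis plants was measured on 24 Affymetrix ATH1 arrays, 1 array per sample, in 8 groups of 3 independent biological replicates, per the labels. Plants grown under 14 h of light and 10 h of darkness were sprayed with 100 µM DCA (3,5-dichloroanthranilic acid), with 100 µM INA (2,6-dichloroisonicotinic acid) or with dilute DMSO in water as the mock treatment. They were harvested after 48 h or after 6 d, per the labels. Col-0 received all 3 treatments at both times, and the mutant npr1-3 received DCA and mock at 48 h.

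The deposited values are linear signal intensities made by the authors with the Affymetrix software GCOS, per the submitters' processing notes, which give no version of it. The deposited signal of each array had been scaled by the authors to a common trimmed mean: leaving out 2% of the values at either end, it was 500.1 on all 24 arrays. No array was scaled again, and no detection calls were used, so a low signal was not sorted into present or absent. The number of arrays, 3 in each group, limits the precision, and so do the differences between replicates of a group. All 24 columns were mapped to a sample, and 0 were left unmapped.

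Signals under 1 were set to 1 and log2 was taken. Of the non-control probe sets, 22746 in number after 64 controls were left out, 13648 had a mean log2 value at or above the 40th percentile of such means, a signal of 74.2, and were tested. A means model of the 8 groups was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which gave 16 residual degrees of freedom and a median prior of 4.44. From it came 8 comparisons of 2 groups and 3 interactions. Tests were two-sided. The p-values were adjusted by Benjamini and Hochberg within each of the 11 comparisons, and a probe set was called at an adjusted p under 0.05. Adjusted p-values for single genes come from limma. Errors of log2 changes are standard errors and those of signals are standard deviations over 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

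A probe set was named only through the supplied platform annotation, which gives 1 gene for 13513 probe sets, several genes for 503 and lists no entry for 8730. Of the tested probe sets, 7334 had 1 gene, 272 had several and 6042 had no entry. A probe set without an entry is unnamed here, not without a gene. Of the probe sets with 1 gene, 13484 matched a RefSeq record of assembly TAIR10.1, which served for symbols only. The build behind the probe annotation is not given in the sources used here, so no coordinates are printed. The probe sets of NPR1, PR1, PR2, PR5, WRKY70, LURP1 and ICS1 have no entry, so no values are given for these genes.

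The genes named per comparison are the 5 largest rises and 5 largest falls that were called, had 1 gene in the annotation, showed no overlap between the arrays of both groups, and had a highest group mean above the median signal of all non-control probe sets, 131. To these come up to 4 called members of each gene list, or up to 2 with the highest mean where none was called, and CaBP22, the one gene of a list of 8 always to be reported that has a probe set in the annotation. Where a list gives many such genes, the text gives those that bear on the comparison and summarises the rest.

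Gene lists with fixed members numbered 420 members, of which 71 had a probe set in the annotation and 49 were tested. They cover SA (salicylic acid) response and systemic acquired resistance, SA synthesis with the EDS1 pathway, WRKY transcription factors, ER folding and secretion, tryptophan synthesis, camalexin and indole glucosinolates, aliphatic glucosinolates, jasmonate and ethylene defence, glutathione transferases, receptor-like kinases of pattern recognition, nuclear-encoded photosynthesis, cell cycle, anthocyanin synthesis, auxin response, cold and abscisic acid response, the circadian clock, markers of root, vascular and guard cell tissue, and reference genes. Lists of heat shock genes, NLR (nucleotide-binding leucine-rich repeat) immune receptors, other detoxification, senescence and flowering had 0 tested members and gave no value. Because so few members could be named, 11 lists were added after the annotation was seen: cytochrome P450s, UDP-glycosyltransferases, expansins with xyloglucan endotransglucosylases, cytosolic ribosomal proteins, TIR-NLR and CC-NLR family loci, LRR receptor kinases of subfamily I, small heat shock proteins, entry into the secretory pathway, amino acid breakdown in darkness, plastid-encoded photosynthesis and plastid-encoded gene expression. The NLR family list and the small heat shock list were written after single loci of these families had been seen among the most changed, and the amino acid breakdown list after MCCA and IVD, which are not in it, had been seen to differ between replicates. A gene with several probe sets is represented by the one with the highest mean. The 19 lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists within each comparison, with camera at an estimated correlation beside it. Fry, also in limma, tested sets of probe sets chosen from another time point, adjusted over 9 such tests.

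The comparisons, the named-gene rule, the fixed lists and all alternatives but 2 were chosen before the data were examined. The alternatives were an offset of 16 or of 64 added before log2, quantile normalization, no filter or a filter at the 60th percentile, no intensity trend, a fit to the compared groups only, the replicate number as a block, and leaving out each array in turn. A minimum change of 2-fold and camera's estimated correlation were tried as well. Removing all replicate 1 arrays and adjusting for a score of the replicate difference over 500 probe sets were added after seeing the data.

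Whether replicate numbers pair the arrays was checked by correlating, across probe sets, the deviations of same-numbered arrays from their group means. All 3 correlations were above 0.1 for Col-0 mock and INA at 48 h (0.76, 0.78 and 0.29), DCA and INA at 6 d (0.75, 0.57 and 0.46), npr1-3 mock and DCA (0.67, 0.66 and 0.12), and Col-0 and npr1-3 mock (0.36, 0.32 and 0.1003). In these comparisons the numbers pair the arrays, on the data's evidence and not by a statement in the labels.

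The fit was tested on simulated data for the comparison of DCA with mock at 48 h over 13648 probe sets, in 20 draws with 200 changed probe sets each. It recovered 37.4% of 2-fold changes and 90.6% of 4-fold changes, with 5.05% of its calls false and 0 in the wrong direction. Of the simulated lists with 33 members, the moved one was called in 20 of 20 draws and 0 unmoved ones were called. The simulated errors were independent between probe sets and between arrays. These rates therefore leave out the replicate differences of the real arrays and any correlation within lists.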

Results

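Transcript levels in the aerial tissue of Arabidopsis were measured on 24 ATH1 arrays, with 3 arrays in each of 8 groups. DCA and INA are dichlorinated aromatic acids that act as synthetic elicitors of plant defence. They were sprayed at 100 µM, and mock plants received the solvent. The Col-0 groups were DCA, INA and mock at 48 h and at 6 d, and the groups of npr1-3, a mutant in NPR1, a coactivator of salicylic acid (SA) responses, were DCA and mock at 48 h. All arrays had the same trimmed mean signal of 500.1, and their median signals ran from 115.1 to 148.4. The number of arrays limits the precision: the median 95% interval of a log2 change reached 0.59 to either side, a factor of 1.5, and that of an interaction reached 0.83, a factor of 1.78.

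The first comparison asks which transcripts DCA changes in Col-0 at 48 h. DCA raised transcripts of defence. The calmodulin-like gene CaBP22 (AT2G41090), a member of the SA response list, rose from a signal of 3469 ± 656 in mock to 15650 ± 1050 (SD, n = 3), a log2 change of 2.19 ± 0.3 (SE; adjusted p 0.00044). The glutaredoxin gene GRX480 rose 5.84-fold (adjusted p 0.0454) and the EDS1 partner SAG101 rose 2.05-fold (0.0277). Of the 33 measured loci of the NLR immune receptor families, 9 were called higher and 0 lower, 29 had a positive change, and their median change was 0.62. The largest of the called ones were AT5G58120 at 11.3-fold (adjusted p 0.0189) and AT3G04210 at 8.35-fold (0.0355), followed by AT1G66090 at 3.93-fold (0.00304) and AT1G72900 at 3.36-fold (0.0201). The fold change of AT5G58120 rests on dim mock signals of 22.3, 55.9 and 36.6 in replicates 1, 2 and 3, each under the filter signal of 74.2. With DCA its signals were 416, 389 and 410. It also differed between replicates with INA at 48 h, at 93.2, 440 and 204.

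Of the 13648 probe sets, limma called 329 in this comparison, 270 higher and 59 lower, of which 231 and 29 changed at least 2-fold. The largest rise was that of the P-type ATPase gene AT3G25610, from 20.72 ± 2.3 to 285 ± 65.3, a log2 change of 3.76 ± 0.61 (adjusted p 0.00173). AT5G52760, which encodes a heavy-metal-associated domain protein, rose 9.96-fold (0.00627) and the EF-hand gene AT3G01830 rose 9.79-fold (0.00688). The largest falls were AT1G62510 (9.47-fold, adjusted p 0.0207), AT5G49170 (5.8-fold, 0.0159), AT1G23050 (4.73-fold, 0.0396), AT5G03230 (4.31-fold, 0.0392) and AT5G66590 (3.89-fold, 0.0417). AT2G04400, an indole-3-glycerol phosphate synthase gene of tryptophan synthesis, rose 2-fold (0.0396), and the coatomer gene AT1G30630 rose 1.74-fold (0.0324). In each of 6 fits that left out 1 of the 6 arrays, AT3G25610, AT5G52760, CaBP22 and AT1G66090 were called. AT3G01830 lost its call without mock replicate 3 (adjusted p 0.053), AT5G49170 lost it in 3 fits, AT1G72900 in 4, and the other genes of this comparison named above in 5, with adjusted p-values of up to 0.303. In a fit to these 6 arrays alone SAG101, AT1G30630, AT5G49170, AT1G23050, AT5G03230 and AT5G66590 were not called (0.0846 to 0.125).

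Among the gene lists at 48 h of DCA, the SA response list (3 measured) had 2 members called, 3 when adjusted over the list alone, a median change of 2.19 and an adjusted camera p of 6.3e-05. The NLR family list, written after single loci of it had been seen among the most changed, had 13 called when adjusted over the list alone (camera 5.17e-09). Both held with an estimated correlation (0.0111 and 0.0012). The cytochrome P450 list (11 measured) had 0 called, 2 when adjusted over the list alone, and a median of 0.45 (0.0146), plastid-encoded gene expression (17 measured) a median of 0.61 (0.00403), and the auxin response list (4 measured, 0 called) a median of -1.72 (0.0494). These 3 did not hold with an estimated correlation (0.0619, 0.456 and 0.456), and auxin response was not called after quantile normalization (-1.69, 0.0577) or with all replicate 1 arrays removed (-0.76, 0.361). Within mock, the auxin response gene IAA29 differed between replicates, with signals of 2324, 98.23 and 1410 in replicates 1, 2 and 3, against 76.93, 109.5 and 332.4 with DCA. The WRKY list (3 measured) had 0 called and 1 when adjusted over the list alone (median 0.48, adjusted p 0.23), ER folding (4) 0 and 1 (0.34, 0.0758), and entry into the secretory pathway (34) 1 and 2 (0.19, 0.0586). The 5 loci of amino acid breakdown in darkness had a median of -0.8 (0.0576).

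The remaining lists tested at 48 h of DCA had 0 members called over all probe sets and no camera call. Their medians were 0.68 for 5 glutathione transferases (adjusted p 0.205), 0.16 for 42 plastid-encoded photosynthesis genes (0.402), 0.07 for 52 cytosolic ribosomal protein genes (0.434), -0.1 for 23 UDP-glycosyltransferases (0.589), 0.08 for 3 cell cycle genes (0.691) and -0.22 for 3 reference genes (0.589). In 4 lists the signs differed: nuclear-encoded photosynthesis (8 measured) had a median of 0.01 and small heat shock proteins (5 measured) one of 0.07, with a test pointing down in both (each 0.949), the 16 expansins and xyloglucan endotransglucosylases a median of 0.07 but a mean of -0.03 (0.64), and cold and abscisic acid response (3 measured) a median of -0.15 but a mean of 0.09 (0.949). In lists too small to test, SAG101 of SA synthesis and AT2G04400 of tryptophan synthesis, each the 1 measured member, were called as given above, and no other member was: the measured jasmonate defence genes PDF1.2 and PDF1.2b changed by 2.25 and 1.8 (adjusted p 0.342 and 0.574), the median of both aliphatic glucosinolate genes was 0.4, and the changes of single members were 0.78 for camalexin and indole glucosinolates, 0.49 for anthocyanin synthesis, 0.3 for receptor-like kinases, 0.02 for the clock gene GI, and -0.11, 0.05 and -0.11 for root, vascular and guard cell markers. Of the 2 measured LRR receptor kinases of subfamily I, 0 were called and 1 when adjusted over the list alone.

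The count of 329 depended on single arrays. Without mock replicates 1, 2 and 3 it was 146, 715 and 117, and without DCA replicates 1, 2 and 3 it was 114, 107 and 147. Replicate 1 and replicate 2 of the mock group differed by over 2-fold in 19% of the probe sets, against 0.901% in the DCA group. On a score of that difference, taken over the 500 probe sets with the largest difference of one sign in all groups at 48 h other than Col-0 DCA, the mock arrays lay at 1.49, -0.79 and 0.2 and the DCA arrays at -0.69, -0.68 and -0.47. With this score as a covariate 373 probe sets were called, of which 271 were among the 329, and with all replicate 1 arrays removed 220, of which 166 were.

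**Figure D1:**
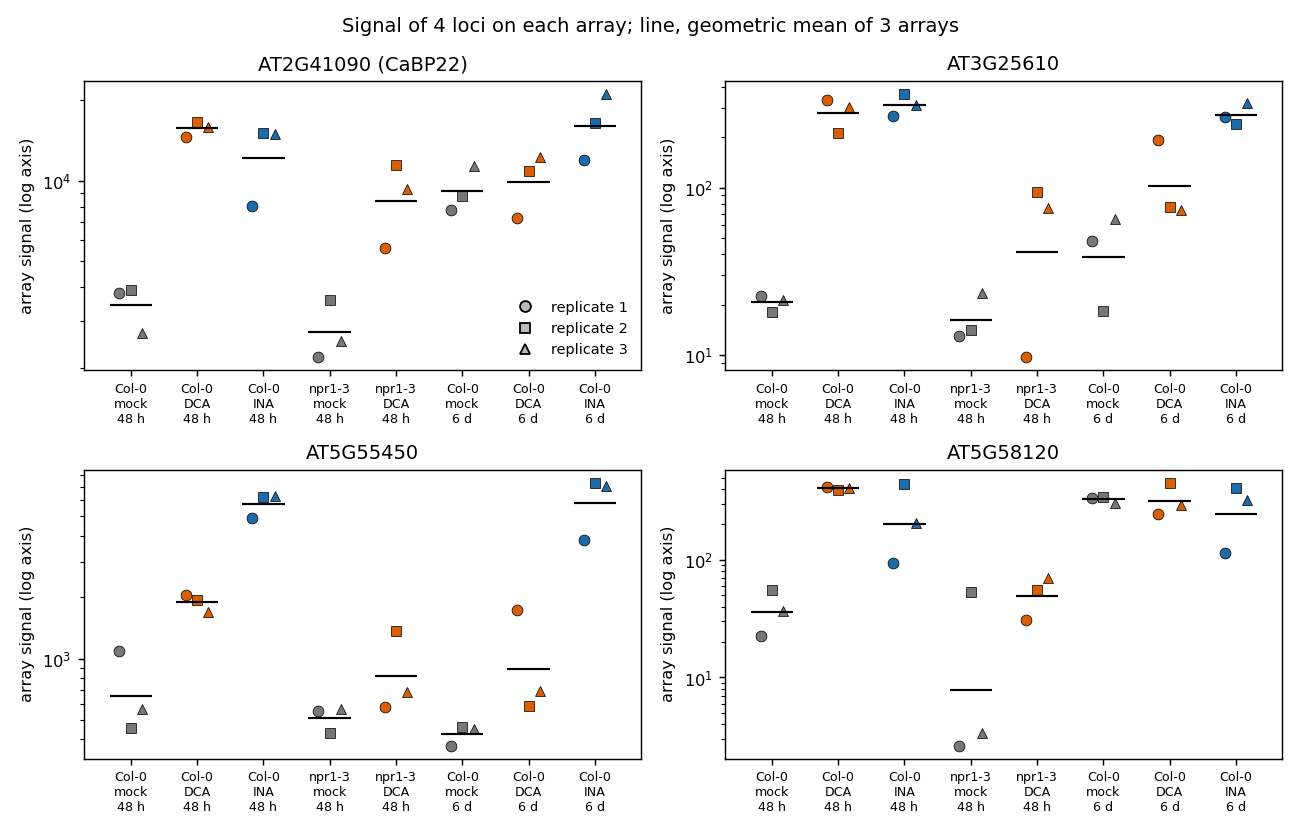
Signal (log axis) per array of CaBP22 (AT2G41090), AT3G25610, AT5G55450 and AT5G58120 in the 8 groups, with a line at the geometric mean of 3 arrays. CaBP22 averaged 3469 in Col-0 mock and 15650 after DCA at 48 h, and 9299 and 10120 at 6 d.

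The same question for INA at 48 h gave a defence response as well. All 3 measured SA response genes were called higher: CaBP22 rose 3.55-fold to 12630 ± 4000 (SD, n = 3; adjusted p 0.000704), GRX480 rose 5.55-fold (0.0495) and SARD4 (AT5G52810), a reductase gene of pipecolic acid synthesis, rose 4.04-fold (0.00774). SAG101 rose 2.2-fold (0.0109) and the transcription factor gene WRKY6 rose 2.89-fold (0.00423). The cytochrome P450 gene CYP71B23 rose 6.19-fold (0.000392) and the glycosyltransferase gene UGT87A2 rose 4.21-fold (0.00228), while UGT85A5 fell 1.88-fold (0.023). Of the 33 NLR family loci 30 had a positive change (median 0.59), and 3 were called higher: AT4G14610 (8.27-fold, 0.00672), which the reference lists as a transcribed pseudogene, AT5G36930 (3.01-fold, 0.0122) and AT1G72900 (2.87-fold, 0.0387).

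For INA at 48 h, limma called 362 probe sets, 324 higher and 38 lower, of which 286 and 16 changed at least 2-fold. The largest rises were AT3G25610 (log2 change 3.92 ± 0.61, adjusted p 0.000509), AT5G52760 (13.2-fold, 0.00116), the protein kinase gene AT1G66880 (12.5-fold, 0.000193), AT3G01830 (9.98-fold, 0.00361) and the ankyrin-repeat gene AT1G10340 (8.83-fold, 4.1e-05). The largest falls were the thionin gene THI2.2 (3.28-fold, 0.00472), AT2G43535 (2.9-fold, 0.0405), AT2G41990 (2.7-fold, 0.0251), AT4G25780 (2.64-fold, 0.024) and AT2G29300 (2.49-fold, 0.0177). The 5 largest rises, THI2.2, SARD4, CaBP22, WRKY6, CYP71B23, UGT87A2 and AT4G14610 were called in all 6 fits that left out an array. SAG101 lost its call without mock replicate 2 (adjusted p 0.0696), UGT85A5 and AT1G72900 lost theirs in 6 fits (highest 0.0971 and 0.16), GRX480 and AT2G41990 in 5 (0.214 and 0.156), AT2G43535, AT4G25780 and AT2G29300 in 4 (0.223, 0.124 and 0.0963), and AT5G36930 in 3 (0.104). In a fit to these 6 arrays alone WRKY6 (0.0944), CYP71B23 (0.117), UGT87A2 (0.0732) and AT4G14610 (0.223) were not called, nor were SAG101, GRX480, UGT85A5, AT2G43535, AT2G41990, AT2G29300, AT5G36930 and AT1G51790 (0.0706 to 0.242).

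Among the lists at 48 h of INA, camera called SA response (median 2.01, adjusted p 3.6e-06), the NLR family (1.28e-07; 8 called when adjusted over the list alone), cytochrome P450s (median 0.32, 0.00127; 1 called, 2 adjusted over the list alone) and entry into the secretory pathway (median 0.24, 30 of 34 positive, 0 called, 0.00339). These 4 held with an estimated correlation (0.00446, 0.00355, 0.0167 and 0.0261), though the NLR list was written after single loci of it had been seen among the most changed. Expansins with xyloglucan endotransglucosylases (median -0.29, 0.0229; 0 called, 3 lower adjusted over the list alone), cold and abscisic acid response (-0.89, 0.0229; 0 and 1), plastid-encoded photosynthesis (-0.5, 41 of 42 negative, 1.35e-08) and plastid-encoded gene expression (-0.54, 4.8e-06; 0 and 2) fell at the preset correlation but not with an estimated correlation (0.102, 0.134, 0.133 and 0.102). WRKY factors (median 1.53, 1 called, 2 when adjusted over the list alone, 0.0547) and ER folding (0.31, 0.0794) missed the threshold and passed it with replicate number as a block (0.0456 and 0.0283), but not with an estimated correlation (0.133 and 0.441). Of the 2 measured LRR receptor kinases 1 was called, AT1G51790 (2.65-fold, adjusted p 0.0166; lost in 4 fits that left out an array, up to 0.0939), and the UDP-glycosyltransferase list had a median of 0.15 and a test pointing down (0.986). The replicate numbers pair these arrays. With them as a block, 606 probe sets were called (481 higher and 125 lower), 360 of them shared with the 362, and AT2G04400, a 0.85 rise with an adjusted p of 0.0904, passed at 0.0305. Without INA replicate 3 and without mock replicate 3 the count was 221 and 236, and 167 with a fit to these 6 arrays alone.

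DCA and INA are structurally related, and their comparison at the same dose and time asks whether the responses differ. DCA and INA raised many of the same transcripts: both raised 183 probe sets at 48 h, where independent calls would share 6.41, both lowered 4 (0.164), and 0 were called in opposite directions. The correlation of the log2 changes across probe sets, which are not independent replicates, was 0.56, against 0.5 in simulations of unchanged groups sharing these mock arrays, and the covariance was 0.148 against 0.061. The share of changes with the same sign was 65.1%, against 66.7% in the simulations. These took the spread pooled over groups, and the spread of these mock arrays themselves gives a covariance of 0.081, or 0.021 when same-numbered arrays deviate together, as mock and INA arrays do at 48 h. The 3 shared mock arrays cannot be split into parts of at least 2, so part of the excess may come from them. The 212 probe sets that INA raised at 6 d were chosen by a change between 6 d arrays. The 48 h arrays entered that choice through the filter and the pooled spread. Over this set the median change at 48 h was 1.01 with DCA (202 positive, fry p 2.21e-06, adjusted over 9 tests 4.97e-06) and 1.54 with INA (212 positive, 5.19e-09, adjusted 4.67e-08). The direct difference over this set had a median of -0.57 (0.00161, adjusted 0.00242), so DCA raised these probe sets less than INA did. A set chosen by a rise with INA favours INA, and no set chosen by a rise with DCA was tested. The difference therefore does not show a weaker response to DCA in general.

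Between DCA and INA at 48 h limma called 0 probe sets, while 1623 had an unadjusted p under 0.05 and the lowest adjusted p was 0.242. CaBP22 differed by 0.36 ± 0.3 (95% interval -0.25 to 0.98, adjusted p 0.609), and GRX480 by 0.07 (-1.31 to 1.46), so differences up to these bounds stay open. Without INA replicate 2 there were 43 calls (14 higher and 29 lower), without INA replicate 3 there was 1, and a fit to these 6 arrays alone called 11, with 2013 at an unadjusted p under 0.05. Camera called plastid-encoded gene expression (median 1.17, 17 of 17 positive, 1.14e-15; 0 called, 13 adjusted over the list alone) and plastid-encoded photosynthesis (0.79, 7.72e-13; 0 and 12) higher with DCA than with INA, auxin response lower (-2.55, 0.00374; 0 and 3) and cold and abscisic acid response higher (1.54, 0.0433). With an estimated correlation, plastid-encoded gene expression held (0.0189) and the other 3 did not (0.227, 0.367 and 0.367). With all replicate 1 arrays removed, the median of auxin response was -1.41 (0.0901) and that of cold and abscisic acid response 0.64 (0.0571), neither of them called, and the latter was not called after quantile normalization either (0.0571). The INA arrays lay at 1.77, -0.75 and 0.2 on the replicate score and the DCA arrays at -0.69, -0.68 and -0.47. The SA response list had a median of 0.07 and a mean of -0.08 (0.993), and the NLR list a median of 0.17 (0.312).

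At 6 d the question is whether the responses persist. After INA, the protease gene AT3G51330 was 16.3-fold higher (adjusted p 0.000198) and the lipid-transfer family gene AT5G55450 rose from 426.6 ± 46.3 to 6068 ± 1930 (SD, n = 3), a log2 change of 3.78 ± 0.38 (3.73e-05). Other genes higher were AT1G66880 (10.9-fold, 0.000669), AT1G26380, which encodes a FAD-linked oxidoreductase of the berberine bridge enzyme family (9.79-fold, 0.006), AT1G72060 (9.17-fold, 0.0328), CYP71B23 (8.08-fold, 0.000174), CYP71B24 (3.41-fold, 0.0107), UGT87A2 (3.6-fold, 0.00968) and the SEC61 beta gene AT3G60540 (3.67-fold, 0.0132). CaBP22 was 1.74-fold higher, with a log2 interval of 0.18 to 1.42, and was not called (0.197), though it was with the replicate score as a covariate (log2 change 1, adjusted p 0.0188). Its mock signal was 9299 ± 1840 at 6 d, against 3469 ± 656 at 48 h. The largest falls were the small heat shock genes AT2G29500 (5.41-fold, 0.00623) and AT1G54050 (4.03-fold, 0.036), AT3G28220 (4.06-fold, 0.000827), THI2.2 (3.05-fold, 0.0128) and AT3G60290 (2.82-fold, 0.00651), and the plastid gene ndhI fell 1.8-fold (0.0145).

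For INA at 6 d, limma called 250 probe sets, 212 higher and 38 lower, of which 185 and 16 changed at least 2-fold. Of the 212, 148 had been raised by INA at 48 h (5.03 with independent calls). AT3G51330, AT5G55450, AT1G66880, CYP71B23, AT2G29500, AT3G28220 and AT3G60290 were called in all 6 fits that left out an array. AT1G26380 lost its call without mock replicate 2 (adjusted p 0.0553), THI2.2, CYP71B24, UGT87A2, AT3G60540 and ndhI lost theirs in 3 fits (up to 0.105), and AT1G72060 and AT1G54050 in all 6 (up to 0.137). In a fit to these 6 arrays alone AT3G60290 (0.0557), CYP71B24 (0.0677), UGT87A2 (0.0668) and ndhI (0.0581) were not called. The count was 127 without mock replicate 1, 120 without mock replicate 2, 160 without INA replicate 2 and 161 without INA replicate 3. Camera called cytochrome P450s higher (median 0.32, adjusted p 0.00133; 2 called, 3 adjusted over the list alone), and this held with an estimated correlation (0.0391). SA response (0.8, 0.0256; 0 called, 2 adjusted over the list alone) and entry into the secretory pathway (0.19, 0.017) were called higher, and expansins with xyloglucan endotransglucosylases (-0.55, 0.017), small heat shock proteins (-0.42, 0.017), plastid-encoded photosynthesis (-0.53, 3.78e-07) and plastid-encoded gene expression (-0.78, 2.08e-06) lower, but not with an estimated correlation (0.142, 0.115, 0.115, 0.215, 0.215 and 0.115). The NLR list had a median of 0.13 (0.174). With all replicate 1 arrays removed, the medians of SA response, expansins and small heat shock proteins were 1.28, -0.3 and -0.61 (camera 0.00016, 0.0474 and 7.72e-05).

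After DCA at 6 d, limma called 0 probe sets, with 444 at an unadjusted p under 0.05 and a lowest adjusted p of 0.701. A fit to these 6 arrays alone also called 0, with 754 at an unadjusted p under 0.05, and the fit without DCA replicate 1 called 1. At 6 d replicates 1 and 2 differed by over 2-fold in 15.6% of the probe sets with DCA and 16.4% with INA, against 1.41% in mock. CaBP22 had a signal of 10120 ± 2590 against 9299 ± 1840 in mock (log2 interval of the change -0.51 to 0.72, adjusted p 0.971), and its change of 0.11 became -0.01 without mock replicate 1 and -0.05 without DCA replicate 3. Over the 324 probe sets that INA had raised at 48 h, the median change at 6 d was 0.28 with DCA (258 positive; fry p 0.0268, adjusted over 9 tests 0.0345) and 1.08 with INA (320 positive; 1.81e-08, adjusted 8.14e-08). The changes by DCA and INA at 6 d correlated across probe sets at 0.73, against 0.5 in simulations with these shared mock arrays, with a covariance of 0.143 against 0.061. The spread of these mock arrays themselves gives a covariance of 0.029, and 0.069 when same-numbered arrays deviate together, as DCA and INA arrays do at 6 d. Part of the excess may therefore come from the shared mock arrays, which are too few to split, and from the replicate numbers. The DCA changes at 48 h and at 6 d correlated at -0.18 over all probe sets, with 41.8% of the same sign, against 0 and 50% in simulations of independent arrays. Their covariance was -0.035. Same-numbered arrays of mock at 48 h and DCA at 6 d deviated together, which by itself gives a covariance of -0.016 with no change. Camera called cytochrome P450s higher (0.31, 0.0308) and cell cycle (-0.63, 0.0308) and ribosomal proteins (-0.1, 0.0308) lower, none of them with an estimated correlation (0.141, 0.638 and 0.908). The NLR and SA response lists had medians of 0 and 0.11 (both 0.858), and auxin response one of 1.02 (0.0887).

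Compared directly at 6 d, probe sets that INA had raised were lower with DCA than with INA. AT5G55450 was 6.57-fold lower (log2 difference -2.72 ± 0.38, adjusted p 0.00202), at 1004 ± 641 with DCA. The ascorbate oxidase-like gene AT4G39830 was 4.94-fold lower (0.0264), the ubiquitin ligase gene RING1 4.11-fold (0.0305), the receptor kinase gene AT1G35710 3.64-fold (0.0242) and UGT87A2 3.51-fold (0.0494). Over the 324 probe sets that INA raised at 48 h the median difference was -0.79 (fry p 8.34e-07, adjusted over 9 tests 2.5e-06). CaBP22 differed by -0.69 (-1.31 to -0.08, adjusted p 0.742).

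In this comparison limma called 29 probe sets, 1 higher and 28 lower. AT5G55450 was called in all 6 fits that left out an array, and the other 4 genes lost their calls in 4 or 5 of them, with adjusted p-values of up to 0.345. The count was 47, 9 and 6 without DCA replicates 1, 2 and 3, and 110, 6 and 4 without INA replicates 1, 2 and 3. The replicate numbers pair these arrays, and with them as a block 62 were called (4 higher and 58 lower). A limma fit to these 6 arrays alone called 0, AT5G55450 (0.219) included, with 659 at an unadjusted p under 0.05. With DCA, camera called SA response (median -0.95, 0.00497), ER folding (-0.54, 0.00129), cytochrome P450s (-0.18, 0.0178; 0 called, 2 adjusted over the list alone) and entry into the secretory pathway (-0.2, 0.00497) lower, and expansins (0.52, 14 of 16 positive, 0.00155), cold and abscisic acid response (0.91, 0.00287), plastid-encoded photosynthesis (0.32, 4.41e-08) and plastid-encoded gene expression (0.55, 17 of 17 positive, 2.15e-10) higher. With an estimated correlation, entry into the secretory pathway (0.0478), expansins (0.0468) and plastid-encoded gene expression (0.0468) held, and SA response, cytochrome P450s and cold response (each 0.0621), ER folding (0.102) and plastid-encoded photosynthesis (0.162) did not. The UDP-glycosyltransferase list had a median of 0 and a mean of -0.09 (0.787), and the NLR list a median of -0.21 (0.121).

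**Figure D2:**
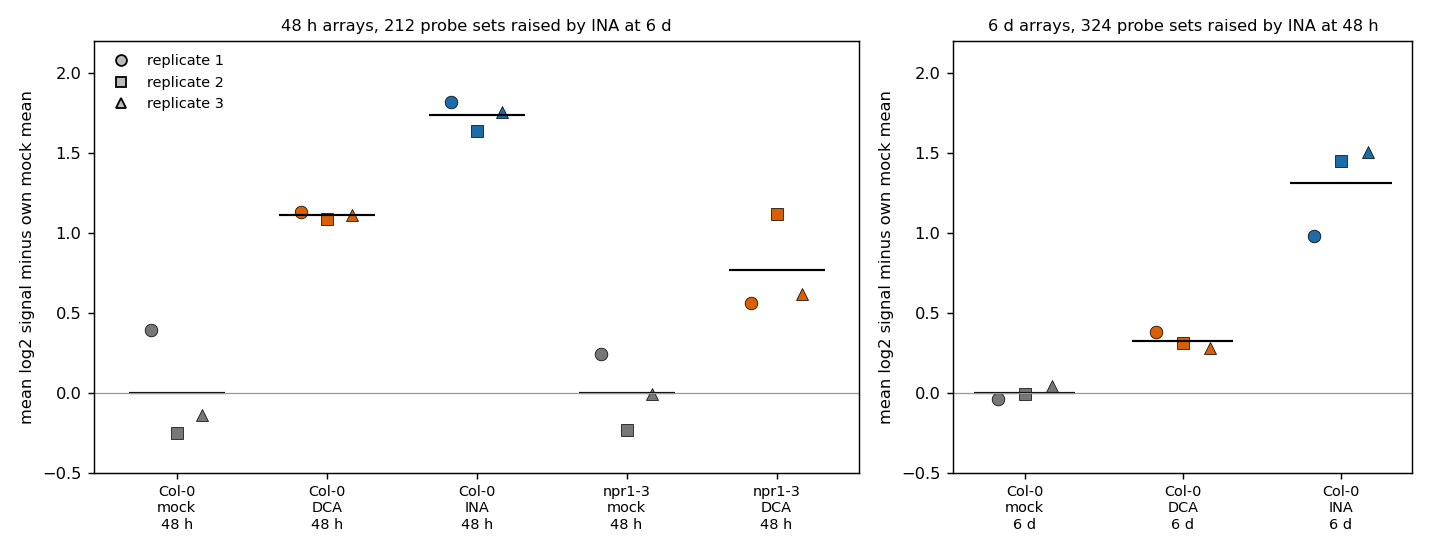
Mean log2 signal per array minus the mean of its own mock group: left, 48 h arrays over the 212 probe sets raised by INA at 6 d; right, 6 d arrays over the 324 probe sets raised by INA at 48 h, with lines at group means. At 48 h the Col-0 DCA arrays lay between 1.09 and 1.13 and the INA arrays between 1.64 and 1.82, and at 6 d the DCA arrays lay between 0.28 and 0.38 and the INA arrays between 0.98 and 1.51.

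The change of each response with time was tested as an interaction. For DCA, limma called 3 probe sets, all with a lower change at 6 d than at 48 h. The ankyrin-repeat gene AT4G11000 rose from 28.3 ± 2.45 to 221 ± 15.7 (SD, n = 3) at 48 h and from 88 ± 10.8 to 118 ± 15.5 at 6 d, an interaction of -2.55 ± 0.38 (adjusted p 0.0114). It was not called without DCA replicate 1 at 48 h (0.0652), mock replicates 1 and 2 at 6 d (0.0533 and 0.0621) or DCA replicate 2 at 6 d (0.0659), nor with all replicate 1 arrays removed (-2.58, 0.0618). In each of the 4 fits that left out 1 array 1 probe set was called in all, and 39 were called without mock replicate 2 at 48 h. The other probe sets have no entry in the annotation and were singled out after their values were seen, with interactions of -2.81 (0.0456) and -4.72 (0.00146). CaBP22 had an interaction of -2.08 ± 0.42, from 2.19 at 48 h to 0.11 at 6 d, which missed the threshold (0.0823). It passed without mock replicate 2 at 48 h (0.0448), in a fit to the 4 groups alone (0.0131) and with all replicate 1 arrays removed (0.0223). A limma fit to the 4 groups alone called 36.

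By camera the DCA change fell from 48 h to 6 d in the NLR list (median -0.7, 1.69e-05; 0 called, 5 adjusted over the list alone), in the SA response list (-1.81, 0.00297) and in plastid-encoded gene expression (-0.71, 0.0184), and it rose in auxin response (2.77, 0.0136) and amino acid breakdown (1.56, 0.0388). With an estimated correlation the NLR call held (0.0136) and the others did not (0.0585 for SA response, 0.494 for the rest). The NLR list was written after single loci of it had been seen among the most changed. Its p-values for DCA and INA are therefore not independent of these data. For INA, limma called 0 interactions, with 346 at an unadjusted p under 0.05, a lowest adjusted p of 0.155, and 0 in a fit to the 4 groups alone (332 unadjusted). The interaction of CaBP22 with INA was -1.03 ± 0.42 (adjusted p 1). Camera called a lower INA change at 6 d than at 48 h in the NLR list (-0.35, 0.000416), SA response (-1.03, 0.0161) and small heat shock proteins (-0.24, 0.0325), where a median of -0.06 at 48 h became a deeper fall of -0.42 at 6 d, and with an estimated correlation the NLR call held (0.0452) and the others did not (0.137 and 0.494). The level of the NLR loci in mock plants also differed between the times: the mean log2 signal of the 33 loci was 6.87 ± 0.15 (SD, n = 3) at 48 h and 7.56 ± 0.06 at 6 d, 30 of 33 were higher at 6 d, and after DCA it was 7.74 ± 0.04 and 7.56 ± 0.13. Time was not tested in mock plants, since age and harvest differ with it.

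**Figure D3:**
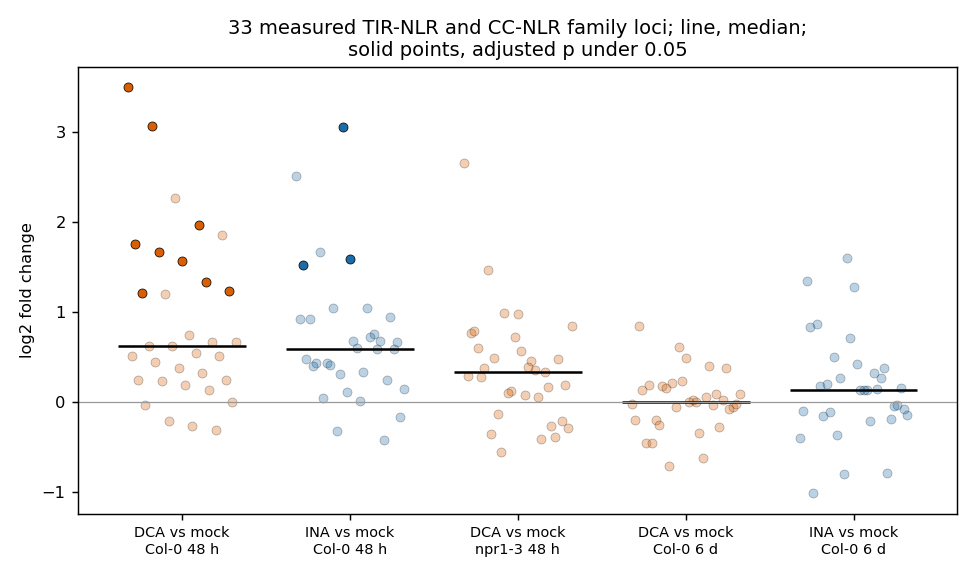
Log2 fold change of the 33 measured NLR family loci in 5 comparisons, with a line at the median and solid points for an adjusted p under 0.05. The medians were 0.62 for DCA and 0.59 for INA at 48 h, 0 and 0.13 at 6 d, and 0.33 for DCA in npr1-3.

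DCA in npr1-3 at 48 h asks how much of the response needs NPR1. The probe set of NPR1 is not named in the annotation and its level was not used to check the labels of the mutant. In npr1-3, CaBP22 rose with DCA from 2773 ± 725 to 8782 ± 2930 (SD, n = 3), a log2 change of 1.63 ± 0.3 (adjusted p 0.0144), and AT1G10340 rose 3.22-fold (0.0479). The pentatricopeptide repeat gene AT1G18900 rose 3.25-fold (0.0121), the protein kinase gene AT5G25440 3.16-fold (0.0121) and the transporter gene AT2G39210 2.73-fold (0.0412). Over the 212 probe sets raised by INA at 6 d, the median change in npr1-3 was 0.69 (195 positive; fry p 0.000171, adjusted over 9 tests 0.000308), against 1.01 in Col-0. The interaction over this set had a median of -0.23 and was not past the threshold (0.147, adjusted 0.147).

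In npr1-3, limma called 44 probe sets, 43 higher and 1 lower. Of the 43, 34 were also raised by DCA in Col-0 (0.851 with independent calls), and across probe sets the changes correlated at 0.42, against 0 in simulations of independent arrays. Deviations of same-numbered Col-0 mock arrays correlated with those of npr1-3 mock (0.36, 0.32 and 0.1003) and npr1-3 DCA (0.38, 0.4 and 0.14). How far this moves the value of 0.42 was not analysed. The count was 76, 11 and 9 without mock replicates 1, 2 and 3, and 11 and 9 without DCA replicates 2 and 3. CaBP22 lost its call without mock replicate 3 (adjusted p 0.084) and without DCA replicates 2 (0.106) and 3 (0.0933), AT1G18900 without mock replicate 2 (0.0696), AT5G25440 in 3 fits (up to 0.0858), and AT1G10340 and AT2G39210 in 5 (up to 0.316). The replicate numbers pair these arrays, and with them as a block 77 were called (71 higher and 6 lower). A limma fit to these 6 arrays alone called 0, with 659 at an unadjusted p under 0.05, and with all replicate 1 arrays removed 165 were called. Camera called SA response higher (median 1.27, 0.00123; 1 called, 2 adjusted over the list alone) and expansins lower (-0.16, 0.0236), neither with an estimated correlation (0.057 and 0.128). The NLR list had 0 called and a median of 0.33 (0.104), and the cytochrome P450 list 0 called, 3 adjusted over the list alone, and a median of 0.23 (0.168).

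The difference of the DCA response between the genotypes was tested as an interaction. CaBP22 differed by -0.56 ± 0.42 (95% interval -1.43 to 0.31, adjusted p 0.961), so a weaker response in npr1-3 by up to 1.43 on the log2 scale was not excluded. The NLR family list had a smaller DCA change in npr1-3 than in Col-0 (median -0.5, camera 1.83e-05), which held with an estimated correlation (0.014). That list was written after single loci of the family had been seen among the most changed, so these p-values are not independent of the data. Plastid-encoded gene expression (-0.54, 0.000333) and plastid-encoded photosynthesis (-0.13, 0.0481) also had a smaller change, but not with an estimated correlation (0.467 and 0.611). SAG101 differed by -1.11 (-1.84 to -0.37, adjusted p 0.961). Of single probe sets limma called 1 (-2.16, 0.0196), which has no entry in the annotation and was chosen after its value was seen. The count was 0 with a fit to the 4 groups alone (568 at an unadjusted p under 0.05), with all replicate 1 arrays removed, and without any 1 of Col-0 mock 1 and 3, Col-0 DCA 1 and 2, npr1-3 mock 3 and npr1-3 DCA 1, and it was 2 without npr1-3 mock 1 and 4 without npr1-3 mock 2.

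Without treatment, npr1-3 differed from Col-0 in a cold response gene. COR15A, which encodes a cold-regulated chloroplast protein, had a signal of 762.7 ± 134 (SD, n = 3) in npr1-3 mock and 5917 ± 3570 in Col-0 mock, 6.69-fold lower (adjusted p 0.0178). The protein kinase genes AT5G25440 and AT5G47070 were 3.23-fold (0.0178) and 2.14-fold lower (0.0109), AT3G01430 was 3.04-fold lower (0.0244) and AT5G26270 was 4.58-fold higher (0.0127). CaBP22 differed by -0.34 (adjusted p 0.706). Over the 212 probe sets raised by INA at 6 d, the median difference was -0.28 (fry p 0.0831, adjusted over 9 tests 0.0935). Replicate 2 of the genotypes stood apart in COR27 (28.91 in npr1-3 mock, 3504 in Col-0 mock) and the clock gene GI (343.1 and 1342). In replicates 1 and 3 COR27 was 3522 and 2382 in npr1-3 mock and 3796 and 4307 in Col-0 mock. Effects of the genotype and of the state at harvest therefore cannot be told apart here.

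In this comparison limma called 11 probe sets, 1 higher and 10 lower. The count was 289 (60 higher and 229 lower) without Col-0 replicate 1, 1 without Col-0 replicates 2 or 3, and 127, 5 and 5 without npr1-3 replicates 1, 2 and 3. With all replicate 1 arrays removed it was 1852, 801 higher and 1051 lower. The replicate numbers pair these arrays, though at a lowest correlation of 0.1003, and as a block they gave 28 calls (4 higher and 24 lower). A limma fit to these 6 arrays alone gave 0, with 914 at an unadjusted p under 0.05. AT5G47070 lost its call without Col-0 replicate 2 (adjusted p 0.0632) or 3 (0.0815), AT3G01430 in 3 fits, and the other 3 genes in 4 (up to 0.247 among all 5). Camera called cold and abscisic acid response lower (median -2.37, 0.00134; 1 called, 2 adjusted over the list alone), plastid-encoded gene expression lower (-0.61, 0.0024) and nuclear-encoded photosynthesis higher (0.27, 0.00329), none with an estimated correlation (0.142, 0.57 and 0.57). The last median was -0.01 after quantile normalization. The expansin list had a median of 0.13 and a mean of -0.11 (0.775).

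**Figure D4:**
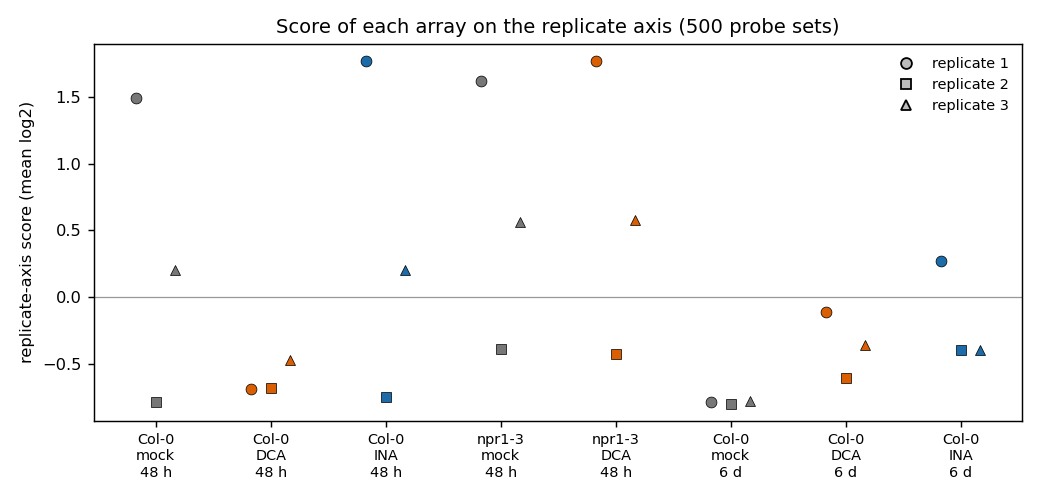
Score of the difference between replicates 1 and 2 per array (mean log2 deviation over 500 probe sets, signed so that replicate 1 is positive), by group. Replicate 1 lay at 1.49, 1.77, 1.62 and 1.77 in Col-0 mock, Col-0 INA, npr1-3 mock and npr1-3 DCA at 48 h, and at -0.69 in Col-0 DCA at 48 h. The probe sets were chosen by this difference in all of these groups but Col-0 DCA, so the high scores follow from the choice. Over all probe sets, the difference in each chosen group correlated with the mean of the other chosen ones at 0.63, 0.72, 0.59 and 0.66. For Col-0 DCA at 48 h the correlation with their mean was 0.01.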

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

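The probe sets and gene lists in this part were singled out by a test of the difference itself, an interaction in limma or camera. Each passed such a test for a difference in the effect of a treatment between genotypes or between time points. The weaker response to DCA than to INA over probe sets that INA raised was not singled out by such a test. The comparison of the DCA response between genotypes over probe sets that INA raised, given below, was not singled out by one either. The tests of explanations were written down before their results were seen, but the rule that sets each value against the spread of the array means was chosen afterwards.

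Limma called 4 probe sets for a different DCA change between groups. A probe set with no entry in the annotation had an interaction with genotype of -2.16 ± 0.32 (SE; adjusted p 0.0196): its signal went from 355 ± 128 to 836 ± 79 (SD, n = 3) with DCA in Col-0 and from 297 ± 37.7 to 164 ± 38.3 in npr1-3. The other 3 were called for a difference between 48 h and 6 d. AT4G11000 had an interaction of -2.55 (0.0114). A probe set without an entry had one of -2.81 (0.0456), with signals of 491 and 4350 in mock and DCA at 48 h and 1160 and 1510 at 6 d. Another without an entry had one of -4.72 (0.00146), with 110 and 632 at 48 h, and 637 and 190 ± 179 at 6 d, where the DCA arrays spread widely. The genotype call was absent with all replicate 1 arrays removed and in a fit to the 4 groups alone. As many calls were made by 10 of 100 splits of the arrays for genotype and 9 of 100 for time with DCA. Chance was therefore not excluded for these calls.

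Camera called several gene lists for a different change as well. Between genotypes, the DCA change was lower in npr1-3 in the NLR list (median -0.5, adjusted camera p 1.83e-05), plastid-encoded photosynthesis (-0.13, 0.0481) and plastid-encoded gene expression (-0.54, 0.000333). Between times, the DCA change was lower at 6 d in SA response (-1.81, 0.00297), the NLR list (-0.7, 1.69e-05) and plastid-encoded gene expression (-0.71, 0.0184), and higher in auxin response (2.77, 0.0136) and amino acid breakdown in darkness (1.56, 0.0388). The INA change was lower at 6 d in SA response (-1.03, 0.0161), the NLR list (-0.35, 0.000416) and small heat shock proteins (-0.24, 0.0325), the last as a deeper fall. Without replicate 1 the median was -1.31 for SA response and -0.88 for small heat shock proteins (camera 2.19e-06 in both). Small heat shock proteins were not called with replicate number as a block (camera 0.1). With an estimated correlation only the 3 NLR calls held. That list was written after single loci of the family had been seen among the most changed, so its p-values are not independent of these data. The auxin and amino acid lists differed between replicates of a group, replicate 1 minus 2 in Col-0 mock at 48 h by a median of 3.93 and 1.39, so a difference in them between groups may come from the harvest. Without replicate 1 the medians of their interactions with time were 1.76 and 0.92, smaller but of the same sign, and no longer called (0.0982 and 0.0716). Harvest stays open for the NLR list too. Its replicate 1 lay below replicate 2 in Col-0 mock and INA at 48 h (means of 6.75 and 7.03, and of 7.32 and 7.8) and in npr1-3 DCA (6.91 and 7.12). The same held at 6 d in DCA (7.42 and 7.69) and INA (7.55 and 7.75). Replicates 1 and 2 were close in npr1-3 mock (6.65 and 6.66) and Col-0 DCA at 48 h (7.78 and 7.74). In mock at 6 d replicate 1 lay above replicate 2 (7.61 and 7.5). Without replicate 1 the NLR medians were -0.3 for genotype (0.000255), -0.34 for time with DCA (4.05e-06) and -0.3 for time with INA (7.37e-05), all still called. Plastid-encoded gene expression was still called without replicate 1 as well, at -0.5 for genotype (0.00513) and -0.39 for time with DCA (0.0375), but its replicates 1 and 2 also differed, by medians of 0.37 in npr1-3 DCA, -0.44 in mock at 6 d and -0.56 in DCA at 6 d (0.04 in Col-0 mock at 48 h), so harvest stays open for it.

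DCA raised the probe sets that INA raised less than INA did at 6 d. Over the 324 probe sets that INA raised at 48 h, the ratio of the median DCA change to the median INA change at 6 d was 0.26. Spread of the replicate 1 arrays is argued against, since without them the ratio was 0.22, and the same ratio taken from array means ran from 0.16 to 0.22 when the mock mean moved by 2 SE. Whether DCA had a weaker effect by the same factor at both times cannot be decided. Over the 212 probe sets that INA raised at 6 d, the ratio at 48 h was 0.66. From array means it ran from 0.53 to 0.71 in the same way. This ratio was higher than that at 6 d, but the ratios were taken over different probe sets. Their ranges also leave out the spread of the DCA and INA arrays. Both sets were chosen by a rise with INA, which favours a ratio under 1, and no set chosen by a rise with DCA was tested. A shorter action of DCA, through uptake, turnover or export of the compound, is a candidate explanation that these arrays did not test.

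The DCA response over the same 212 probe sets had a median of 1.01 in Col-0 and 0.69 in npr1-3, and the interaction over the set was not past the threshold (fry p 0.147). The test of a lower mock level in npr1-3 was void: such a level would make the change larger, not smaller, and the DCA level, lower by a median of -0.59, follows from the mock difference of -0.28 and the smaller response. The light or harvest state of the Col-0 DCA arrays and an effect of the genotype cannot be told apart: without replicate 1 arrays the difference of the responses was 0.3 with 2 SE of 0.57, against 0.32 with 2 SE of 0.6 in all arrays, too wide to decide. A partial need for NPR1 stays open and may be smaller or larger than this difference.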

How the results depend on the processing

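Removing all replicate 1 arrays and adjusting for the replicate score were chosen after seeing the data. Calls of single named genes were compared 1248 times with another setting: 963 kept side and direction, 277 lost the call, 6 gained one and 2 reversed. The reversed ones are the uncalled change of CaBP22 with DCA at 6 d, -0.01 without mock replicate 1 and -0.05 without DCA replicate 3, in a range up to 0.33. Of 204 such comparisons of list calls 154 kept side and direction and 50 lost the call, 37 of them with camera's estimated correlation. The others lost were auxin response in DCA at 48 h (quantile normalization 0.0577, replicate 1 removed 0.361), in DCA against INA at 48 h (replicate 1 removed 0.0901) and in time with DCA (replicate 1 removed 0.0982), and cold response in DCA against INA at 48 h (quantile 0.0571, replicate block 0.0675, replicate 1 removed 0.0571). With replicate 1 removed, cell cycle in DCA at 6 d (0.0584), plastid-encoded gene expression in npr1-3 mock (0.192) and amino acid breakdown in time with DCA (0.0716) were lost too. Quantile normalization ended nuclear-encoded photosynthesis in npr1-3 mock (0.444) and plastid-encoded photosynthesis in the genotype interaction (0.256), and the block ended small heat shock proteins in time with INA (0.1). With a minimum change of 2-fold every count stayed within 1.5 times of the reported one. For the counts of called probe sets that moved by more, the cause was not tested unless the setting itself removes arrays or probe sets.

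Counts are given here in the order in which the reported ones stand: DCA 48 h 329, INA 48 h 362, DCA 6 d 0, INA 6 d 250, DCA against INA 48 h 0 and 6 d 29, npr1-3 DCA 44, npr1-3 mock 11, genotype interaction 1, time interaction with DCA 3 and with INA 0. Leaving out 1 array gave ranges of 107 to 715, 221 to 332, 0 to 1, 120 to 228, 0 to 43, 4 to 110, 9 to 76, 1 to 289, 0 to 4, 1 to 39, and 0 to 0.

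An offset of 16 moved DCA against INA at 6 d to 44 and the time interaction with DCA to 5. An offset of 64 moved DCA against INA to 3 at 48 h and 77 at 6 d, npr1-3 DCA to 27 and the time interaction with DCA to 11. Quantile normalization moved npr1-3 DCA to 25, npr1-3 mock to 18, the genotype interaction to 3 and the time interaction with DCA to 2. With no filter DCA at 6 d had 2, npr1-3 DCA 26 and the genotype interaction 2. With a filter at the 60th percentile DCA against INA at 6 d had 18 and the genotype interaction 2, and without the intensity trend the genotype interaction had 3 and the time interaction with DCA 2.

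A fit to only the groups compared, with fewer arrays behind the spread, gave 167 for INA at 48 h, 11 for DCA against INA at 48 h and 36 for the time interaction with DCA. It gave 0 in limma for DCA against INA at 6 d (659 at an unadjusted p under 0.05), npr1-3 DCA (659), npr1-3 mock (914) and the genotype interaction (568).

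With replicate number as a block, the paired comparisons gave 606 for INA at 48 h, 62 for DCA against INA at 6 d, 77 for npr1-3 DCA and 28 for npr1-3 mock, and no call of a named gene or list in them changed other than those given beside the results. In the others the arrays share only a number. The deviations of same-numbered arrays correlated at -0.1, 0.19 and 0.13 for mock and DCA at 48 h, -0.02, 0.08 and 0.09 at 6 d, 0.02, 0.14 and 0.34 for mock and INA at 6 d, and -0.13, 0.15 and 0.15 for DCA and INA at 48 h, and in none of them did every array correlate best with its own number. There the block gave 945 for DCA at 48 h, 854 for INA at 6 d, 147 for the time interaction with DCA and 2 for that with INA, and CaBP22 was called with INA at 6 d (0.0257) and in the time interaction with DCA (0.00675).

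With all replicate 1 arrays removed, DCA at 6 d, DCA against INA at 48 h and the time interaction with INA had 1 each, DCA against INA at 6 d 130, npr1-3 DCA 165, npr1-3 mock 1852, the genotype interaction 0 (790 at an unadjusted p under 0.05) and the time interaction with DCA 13. With the replicate score as a covariate, INA at 48 h had 652, DCA against INA at 6 d 78, npr1-3 DCA 80, npr1-3 mock 74 and the time interaction with INA 1.

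The background of the arrays is not given in the sources used here and no detection calls were used, so how far a dim signal lay above background was not analysed here.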

Other observations

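The tests of this part were written down before their results were seen. The gene list used for darkness was chosen after MCCA and IVD, which are not in it, had been seen to differ between replicates.

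Leucine breakdown transcripts varied between replicates of the same group. MCCA had a signal of 5229, 796.4 and 3317 in replicates 1, 2 and 3 of Col-0 mock at 48 h, and of 9666, 664.2 and 6291 in npr1-3 DCA, but of 649.2, 490 and 1073 in Col-0 DCA at 48 h. The auxin response gene IAA29 ran from 98.23 to 2324 in Col-0 mock. COR27 had 3522, 28.91 and 2382 in npr1-3 mock and 3924, 53.55 and 2322 in npr1-3 DCA, while in the Col-0 arrays at 48 h it lay between 2180 and 4307.

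This pattern separates replicate 1 from replicate 2 in 4 of the 5 groups at 48 h, all but Col-0 DCA. Harvest in darkness or late in the day for replicate 1 goes with the 5 loci listed under amino acid breakdown in darkness, of which AKINBETA1 encodes a kinase subunit. Their median difference, replicate 1 minus 2, was 1.79 over the 4 groups. MCCB lay at 2.57, ETFQO at 2.25, AKINBETA1 at 1.79, AT4G33150 at 1.63 and D2HGDH at 0.18. Array scaling is argued against: quantile normalization left the share of probe sets over 2-fold apart at 0.977 of its value, 12.1% instead of 12.4%. A different hour is not borne out by the clock gene GI in Col-0, where replicates 1 and 2 were alike at 48 h (1016 and 1342 in mock, 1251 and 1117 with INA), while in npr1-3 they were not (1616 and 343.1 in mock, 1658 and 515.7 with DCA). At 6 d in Col-0, GI differed between replicates 1 and 2 with DCA (1196 and 503.5) and INA (1089 and 458.4). GI was 528.1 and 478.1 in mock at 6 d. As 1 gene, GI does not exclude a different hour. AT3G44450, taken as a light-related gene, was lower in replicate 1 than in replicate 2 in the 4 groups. Its signals were 50.81 and 163.5 in Col-0 mock, 39.32 and 247.3 with INA, 42.91 and 662.4 in npr1-3 mock, and 33.32 and 905.1 in npr1-3 DCA. In Col-0 DCA at 48 h they were 242.6 and 214.7. The hour of harvest is not given in the sources used here, and the design names no group that separates these replicates, so other stresses that deplete sugar stay open.

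Each comparison was set against other splits of its arrays into groups of the same sizes. With 3 against 3 there are 10 splits, too few for a share under 0.05, the real one included. As many calls as in the real split were made by 1 of 10 splits for DCA at 48 h (329, highest other 0), 3 for INA at 48 h (362, 485), 10 for DCA at 6 d (0, 0), 1 for INA at 6 d (250, 0), 10 for DCA against INA at 48 h (0, 0), 2 for the same at 6 d (29, 47), 3 for npr1-3 DCA (44, 756) and 1 for npr1-3 mock (11, 1). The 485 came from mock 1, INA 1 and INA 3 against the rest, the 47 from DCA 1, INA 1 and INA 3, and the 756 from mock 1, DCA 1 and DCA 3, so these splits follow the replicate structure. The numbers pair the arrays in INA at 48 h, DCA against INA at 6 d, npr1-3 DCA and npr1-3 mock, and there, among the 4 splits that part all 3 pairs, the highest count of the others was 0. The blocked counts were 606, 62, 77 and 28.

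For the interactions 100 splits were drawn, and for genotype and for time with DCA chance was not excluded by them. As many calls as in the real split were made by 10 of 100 for the genotype interaction (1, highest other 518), 9 for the time interaction with DCA (3, 110) and 100 for that with INA (0, 953), where every split reaches a real count of 0 and the splits decide nothing. Such splits mix treated and mock arrays within a genotype or time, so the treatments themselves can raise their counts, and which arrays gave the highest ones was not analysed here.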
